A study of Rattus norvegicus with 14 samples.

How the data were processed

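The series holds polyadenylated RNA of rat aortas, dissected from the renal arteries up to the heart, cleared of connective tissue and blood and frozen, per the labels' protocols. There are 14 libraries, 1 per rat: 5 control, 5 uremic (all given vitamin D) and 4 control with vitamin D. Per the submitters' processing notes, the authors used cutadapt 1.3, TopHat2 2.0.10, Cufflinks 2.1.1 and Cuffdiff with the rat genome build rn5; the notes give no settings. Rat 27 has 2 index sequences in its label, while no label gives a batch or a sequencing date.

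The deposited table has 17019 genes with 1 column per library, the mean of each group and a q value per pair of groups. Its header names no unit. The values were read as FPKM, which the authors' tools give. In 10914 of 11294 genes (96.6%) above 0 in at least 8 libraries, the values of all libraries were whole multiples of 1 step per gene and library, within a tolerance of 0.1 read. After shuffling of libraries this held in 0% of 1000 genes. The number of whole reads per gene was recovered from these steps; over all recovered genes a library had between 1331058 and 4535467 reads, and the median gene had 55 per library. No counting intervals are given, because the spread between rats is the error used here, and reads from PCR are not independent molecules. The deposited group means matched the means of the library columns to within a relative gap of 7.3e-06. The authors' q values (p-values adjusted for the number of genes tested) were used only for comparison. Of the gene names, 25 had been turned into dates by a spreadsheet; these genes were tested but not named. In all, 3750 genes were at 0 in every library.

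Calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Each comparison used the libraries of its 2 groups. Genes with at least 1 FPKM in at least 4 of these libraries were tested on log2(FPKM + 1) with limma (lmFit and eBayes with a trend), 2-sided, and called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. SE and adjusted p in the text are those of limma, and folds are ratios of group means. The fit was tested on simulated data: values were drawn around each gene's mean with its fitted SD, and 200 genes were changed. At a change of 1 on the log2 scale the fit recovered 85.9% (uremic against control), 82.5% (control with vitamin D against control) and 81.8% (uremic against control with vitamin D), with 5.37%, 5.60% and 4.43% of the calls false. Each gene was drawn on its own, without the correlation between genes of the real libraries. The adjusted p also depends on how many genes change. These shares therefore do not tell how many changes of this size were missed in the real data.

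The comparisons, tests, alternatives, the rule for named genes and 39 gene lists (pathways, cell types and tissues that a dissected aorta can hold) were fixed before the data were examined. Of the lists, 35 had at least 5 tested members. Lists of heat shock and MHC genes, added after the data were seen, were adjusted together with these, over 38 lists in each comparison. A list was tested with the camera test of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. Member counts are given over all genes and adjusted over the list alone. Some lists share genes, for example 4 of the macrophage list. Named genes are the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 1 and no overlap between the groups; 18 genes fixed for all comparisons; and up to 4 members per list with the smallest p.

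The overlap of the comparisons against control was set beside independent lists, simulated groups without a change and control libraries divided between the comparisons. The counts of called genes were recomputed with other pseudocounts (0.1 and 0.01), other filters, median-ratio, quantile and equal-total scaling, 1 fit for all 3 groups, array weights, a robust fit, a minimum change, an exact 2-sided rank-sum test and without each rat in turn; named genes and lists were recomputed with fewer of these. Added after the data were seen were the brown fat score (8 genes) as a covariate, limma voom on the recovered reads, and the genes with recovered reads alone. The planned test for whole reads other than limma was not run. In 100 of 126 possible splits of the libraries of each comparison the calls were counted again. In each group of 4 or 5 rats, a rat was marked when its gap to the next value, over the range of the group, passed Dixon's 95% critical value.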

Results

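Transcript levels were measured by RNA sequencing in the aortas of 14 male Dark Agouti rats: 5 control rats, 4 control rats given vitamin D and 5 uremic rats given vitamin D. Uremia followed 5/6 nephrectomy, the removal of most kidney tissue, and lasted 14 weeks. The uremic rats received alfacalcidol, a vitamin D prodrug that the liver activates, at 30 ng 3 times a week for the last 6 weeks. For the control rats on vitamin D no source gives the dose or the length of treatment. Their length of study is not given either, while it was 14 weeks for the control and uremic rats. The series notes name a diet rich in phosphate as needed for calcification, without saying which rats received it, so diet may differ between the groups as well. Values are the deposited FPKM (fragments scaled by transcript length and by the reads of the library), with the mean, SD and number of rats. Whole reads recovered from the FPKM steps of 10914 genes summed to between 1331058 in rat 37 (control with vitamin D) and 4535467 in rat 27 (uremic). The median gene and library had 55 reads, and the files give no total read count beyond these genes.

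Uremic libraries stood apart from the rest. The median correlation of log2 values across genes was 0.931 between control and uremic libraries, 0.970 among control libraries and 0.963 among uremic libraries. Between control libraries and those of control rats on vitamin D it was 0.961. Genes are not independent replicates, so these values carry no p. Mgp (matrix Gla protein, an inhibitor of vascular calcification) held 15.8% of all FPKM in uremic libraries (13.3% to 19.5%), 2.44% in control libraries and 2.86% in those of control rats on vitamin D.

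The first comparison, uremic against control, asks which transcripts differ in the aorta when chronic uremia and vitamin D are combined; both differ between these groups, and diet may too. Some genes of bone and cartilage matrix were far higher in uremic aortas, while others were lower or did not pass the test. Most macrophage and complement genes were higher, and many contractile smooth muscle genes were lower. Mgp (chromosome 4, 235113782 to 235117105 in the rn5 build) averaged 78679.5 ± 14872 FPKM in uremic and 11135 ± 2072 FPKM in control aortas (n = 5 each), 7.07-fold higher (log2 2.82, SE 0.29, adjusted p = 3.1e-05). Spp1 (osteopontin, a phosphoprotein that binds mineral; chromosome 14, 6653085 to 6658937) rose from 443 ± 101 to 6552 ± 1833 FPKM (log2 3.86, SE 0.23, adjusted p = 3.8e-07). Sost (sclerostin, a secreted Wnt inhibitor made by osteocytes; chromosome 10, 89689511 to 89692559) rose from 11.5 ± 5.73 to 139 ± 61.2 FPKM (log2 3.49, SE 0.37, adjusted p = 4.4e-05).

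In uremic against control aortas, the osteoblast and osteocyte list had 15 tested members, of which 6 rose and 2 fell (7 and 3 adjusted over the list alone). The list was called higher by the camera test (adjusted p = 0.0142), with adjusted p = 0.322 with an estimated correlation. Ibsp (bone sialoprotein) rose 28.6-fold, from 2.44 ± 1.10 to 69.8 ± 14.0 FPKM, and Mepe, a phosphoglycoprotein of osteocytes, was listed at 0 in all 5 control libraries and averaged 11.1 ± 5.42 FPKM in uremic ones. Runx2, a transcription factor of osteoblast differentiation, rose from 1.33 ± 0.377 to 6.02 ± 1.93 FPKM (log2 1.55, SE 0.22). Alpl (the alkaline phosphatase of bone) and Col1a1 (a chain of type I collagen) went the other way. Col1a1 fell from 1516 ± 277 to 692 ± 434 FPKM, and Alpl fell from 38.0 ± 3.53 to 21.3 ± 11.2 FPKM (adjusted p = 0.0296). The Alpl call held without control rat 46, uremic rat 9 or uremic rat 20, and ended without any of the other 7 rats, with an adjusted p of up to 0.063.

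Among 10 tested chondrocyte genes, 5 rose and 1 fell in uremic against control aortas (5 and 2 adjusted over the list alone; camera adjusted p = 0.00794, and adjusted p = 0.147 with an estimated correlation). Comp, a cartilage matrix protein, rose from 20.4 ± 5.83 to 299 ± 104 FPKM and Prg4 (lubricin) from 7.32 ± 1.37 to 87.3 ± 56.6 FPKM, while Ucma, a Gla protein of cartilage, fell from 6.19 ± 1.82 to 0.225 ± 0.308 FPKM. Of 13 calcification inhibitors and phosphate handling genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.00605, and adjusted p = 0.322 with an estimated correlation). Ankh, which exports pyrophosphate, rose from 25.4 ± 3.29 to 125 ± 51.4 FPKM, and Nt5e, which makes adenosine, from 11.4 ± 1.56 to 50.7 ± 14.8 FPKM. Enpp1, which makes pyrophosphate, rose by 1.26 on the log2 scale (SE 0.19), and the phosphate transporter Slc20a1 by 0.85 (SE 0.18). Bmp2 (log2 0.69, SE 0.32) and Tnfrsf11b (log2 -0.60, SE 0.24) did not pass the test. Vdr, the vitamin D receptor, averaged 3.11 ± 0.757 against 1.33 ± 0.904 FPKM (adjusted p = 0.040); its call held without control rat 41, control rat 46 or uremic rat 17 and ended without any of the other 7 (adjusted p up to 0.090) and with a smaller pseudocount. Cyp24a1, the vitamin D hydroxylase, was listed at 0 in all 14 libraries, Kl and Col2a1 lay below the filter on low values, and Sox9 was not analysed here.

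Contractile smooth muscle genes were lower in uremic than in control aortas: 14 of 24 fell and none rose (17 fell when adjusted over the list alone). The list median was -0.75 on the log2 scale, and camera called it lower (adjusted p = 1.6e-08), with adjusted p = 0.33 with an estimated correlation. Myh11 (smooth muscle myosin heavy chain) fell from 3545 ± 557 to 1724 ± 433 FPKM. Ppp1r14a, an inhibitor of myosin phosphatase, fell from 1038 ± 245 to 385 ± 94.4 FPKM, and Cnn1 (calponin) from 1029.6 ± 127 to 551 ± 127 FPKM. Acta2 (smooth muscle actin) averaged 4257 ± 1509 against 7118 ± 1377 FPKM (adjusted p = 0.0416). Its call held without control rat 46 or uremic rat 17 and ended without any of the other 8 rats (adjusted p up to 0.094).

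**Figure D1:**
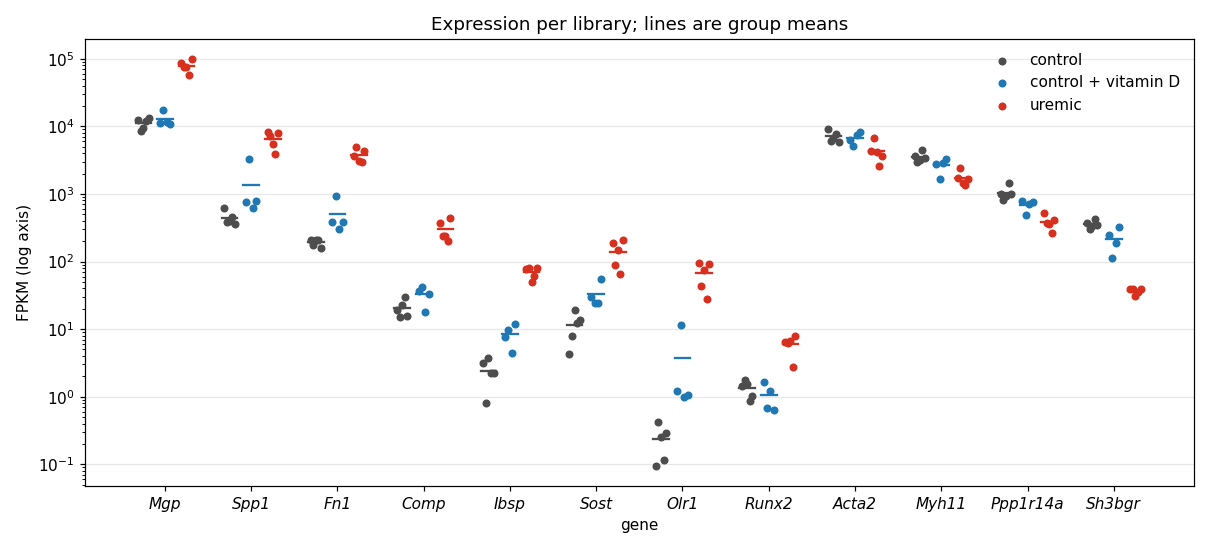
FPKM (log axis) of 12 genes in each of the 14 libraries; points are rats, coloured by group, and lines are group means. For Mgp, Spp1, Fn1, Comp, Ibsp, Sost, Olr1 and Runx2 all uremic points lie above all points of the other groups, and rat 37 is the highest of the control rats on vitamin D for Mgp, Spp1, Fn1 and Olr1.

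Matrix genes moved in both directions in uremic against control aortas. In the fibrillar matrix list 10 of 28 rose and 5 fell (10 and 6 adjusted over the list alone); its median was 0.07, and -0.04 with libraries scaled to the same total. Camera called it higher (adjusted p = 0.0374), with adjusted p = 0.576 with an estimated correlation, and the call ended without control rat 44, uremic rat 20 or uremic rat 28 (adjusted p up to 0.14). Fn1 (fibronectin) rose 19.7-fold, from 192 ± 24.1 to 3778 ± 881 FPKM. Thbs1 (thrombospondin) rose from 1.24 ± 0.701 to 54.3 ± 23.2 FPKM, and Postn (periostin) from 87.4 ± 28.6 to 810.3 ± 192 FPKM. Of 27 BMP and TGF-beta pathway genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 2.4e-04, and adjusted p = 0.171 with an estimated correlation). Ltbp2, which belongs to the family of latent TGF-beta binding proteins, rose from 167 ± 30.5 to 901 ± 239 FPKM and the BMP antagonist Grem1 from 1.39 ± 0.589 to 5.52 ± 1.83 FPKM. The FGF and Klotho list had 9 of 15 members higher and none lower (12 higher adjusted over the list alone; camera adjusted p = 2.9e-05, and adjusted p = 0.147 with an estimated correlation). Etv4, a transcription factor induced by FGF signalling, stood at 0.072 ± 0.10 in control and 5.23 ± 1.66 FPKM in uremic aortas.

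Macrophage genes were higher in uremic than in control aortas: 18 of 20 rose and none fell (20 rose when adjusted over the list alone), with a median of 1.60 on the log2 scale (camera adjusted p = 1.2e-14, and adjusted p = 0.147 with an estimated correlation). Lyz2 (lysozyme) rose from 33.6 ± 15.7 to 263 ± 47.4 FPKM. Gpnmb, a glycoprotein of phagocytes and osteoclasts, rose from 13.6 ± 4.23 to 72.8 ± 21.0 FPKM, and the lysosomal marker Cd68 from 8.69 ± 4.33 to 36.2 ± 8.52 FPKM. Red blood cell genes had a median of 1.61 in the same comparison with 0 of 7 called by limma, and their list call (camera adjusted p = 0.0495, and adjusted p = 0.574 with an estimated correlation) ended without any of 6 rats: control rats 41, 42, 44 and 46 and uremic rats 9 and 27 (adjusted p up to 0.13). Complement genes, 4 of them shared with other lists, had 13 of 16 higher (15 adjusted over the list alone; camera adjusted p = 1.6e-08, and adjusted p = 0.171 with an estimated correlation). Serping1, the C1 inhibitor, rose from 140.0 ± 29.9 to 651 ± 231 FPKM. Of 26 cytokine, chemokine and adhesion genes, 14 rose (15 adjusted over the list alone; camera adjusted p = 4.1e-07, and adjusted p = 0.171 with an estimated correlation). Il6 rose from 0.359 ± 0.251 to 10.7 ± 6.26 FPKM, and the adhesion molecule Icam1 from 12.2 ± 1.73 to 28.0 ± 3.49 FPKM. Cell cycle genes rose from low levels in 15 of 17 cases (16 adjusted over the list alone; camera adjusted p = 1.1e-09, and adjusted p = 0.171 with an estimated correlation). Top2a (topoisomerase) stood at 0.431 ± 0.179 in control and 3.58 ± 0.953 FPKM in uremic aortas.

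Some oxidative phosphorylation genes were lower in uremic than in control aortas. In the oxidative phosphorylation list 11 of 31 fell and none rose (19 fell when adjusted over the list alone; camera adjusted p = 5.2e-08, and adjusted p = 0.524 with an estimated correlation). Cyc1 (cytochrome c1) fell from 47.0 ± 8.95 to 22.2 ± 4.79 FPKM. In the fatty acid oxidation list 1 of 24 fell (0 adjusted over the list alone; camera adjusted p = 0.0030, and adjusted p = 0.574 with an estimated correlation). The glycolysis list was not called, with 2 of 20 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.195). With the brown fat score of each library as a covariate in the fit of all 3 groups, chosen after the data were seen, the oxidative phosphorylation median went from -0.56 to -0.17, and the members called by limma from 6 to 3. Ucp1, the uncoupling protein of brown fat, fell from 87.7 ± 31.2 to 19.1 ± 13.9 FPKM, but the brown fat list was not called (1 of 9 lower, 4 adjusted over the list alone; camera adjusted p = 0.0607). Of 23 adipocyte genes 5 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0426, and adjusted p = 0.662 with an estimated correlation). Under the brown fat covariate the median of 19 adipocyte genes outside the score turned from -0.30 to 0.36. Of these, 6 were called without and 8 with the covariate in the fit of all 3 groups. The brown fat score (mean log2 of 8 marker genes, centred) averaged -0.76 in uremic (-1.62 to 0.10), -0.10 in control (-0.53 to 0.56) and 1.08 in control rats on vitamin D (-0.15 to 2.18). Beyond the lists, Olr1, a receptor for oxidised LDL, had the largest rise among called genes on the scale of log2(FPKM + 1), from 0.235 ± 0.132 to 66.5 ± 29.5 FPKM, and Pnoc, the precursor of nociceptin, rose from 1.3 ± 0.683 to 34.3 ± 12.9 FPKM. The largest falls included the organic cation transporter Slc22a2, from 57.0 ± 7.89 to 3.46 ± 1.52 FPKM, Sh3bgr, from 354 ± 43.7 to 36.8 ± 3.92 FPKM, and Crhr2, a receptor of the corticotropin releasing hormone family, from 12.6 ± 3.51 to 0.653 ± 0.422 FPKM. Jund, an AP-1 transcription factor, fell from 874 ± 158 to 236 ± 53.7 FPKM. Cyp2e1 was called higher at 133 ± 235 FPKM, but uremic rat 27 alone had 551 FPKM against at most 72.2 in the other uremic rats.

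Over all genes, limma called 2177 of 9957 between uremic and control aortas, 1131 higher and 1046 lower, and 421 and 248 of these changed by at least 1 on the log2 scale. In 1563 genes (15.7%; chance gives 0.794%) no uremic library overlapped a control library. The authors' table lists 1905 genes at q under 0.05, 950 higher and 955 lower; 1541 genes were called in both, all in the same direction. Of 35 lists tested with a preset correlation, 19 were called, and none of these calls held with an estimated correlation. With every library scaled to the same total, 34.6% of the called genes were higher, against 52.0% as deposited. Per gene, an exact rank-sum test called 0 after adjustment, where limma called 2177. Before adjustment, 3506 genes had a p under 0.05 in limma.

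The second comparison, control with vitamin D against control, asks what differs in aortas of rats with intact kidneys when vitamin D is given. Diet and length of study are not known to be equal. Limma called 13 of 9693 genes, 1 higher and 12 lower, with 1782 at an unadjusted p under 0.05. Col1a1 fell from 1516 ± 277 FPKM in control (n = 5) to 648 ± 165 FPKM with vitamin D (n = 4; log2 -1.24, SE 0.20, adjusted p = 0.048), and Col3a1, the chain of type III collagen, from 1537 ± 183 to 813 ± 113 FPKM (log2 -0.92, SE 0.15, adjusted p = 0.049). The other named falls were Rcor2, a transcriptional corepressor, from 43.3 ± 11.4 to 15.9 ± 1.49 FPKM, Jund, from 874 ± 158 to 439 ± 72.2 FPKM, and the desaturase Fads2, from 36.6 ± 3.65 to 15.9 ± 4.48 FPKM. The sulfur transferase Tst fell from 48.3 ± 4.05 to 24.7 ± 5.05 FPKM, as did the levels of Nrep, Prrt2, Tnxa-ps1 and Adamts10. Cfd (adipsin, a serine protease made by fat cells) was the gene that rose, from 22.9 ± 8.85 to 69.4 ± 20.7 FPKM (log2 1.57, SE 0.26, adjusted p = 0.049).

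All 13 of these genes were called in the same direction in uremic against control. Mgp, Runx2, Spp1, Sost and Ibsp, higher in uremic aortas, did not pass the test in control with vitamin D against control. Mgp averaged 12730.5 ± 3015 against 11135 ± 2072 FPKM (log2 0.19, SE 0.24), and Runx2 1.05 ± 0.487 against 1.33 ± 0.377 FPKM. Spp1 averaged 1365 ± 1280 against 443 ± 101 FPKM (adjusted p = 0.144), Sost 33.4 ± 14.7 against 11.5 ± 5.73 FPKM (adjusted p = 0.0871) and Ibsp 8.45 ± 3.14 against 2.44 ± 1.10 FPKM (adjusted p = 0.0835). Rat 37 had 3281 FPKM of Spp1, against at most 789 in the other 3 rats on vitamin D. Still, every rat on vitamin D lay above every control rat for Spp1 (lowest 627 against highest 612 FPKM), Sost (24.0 against 19.4) and Ibsp (4.47 against 3.72). Such a lack of overlap held in 5.72% of all tested genes. Of 14 tested osteoblast and osteocyte genes 0 passed over all genes, while 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.934). Acta2 differed by -0.07 (SE 0.22) and Enpp1 by -0.09 (SE 0.24) on the log2 scale, and the sign of both turned when single rats were left out.

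Fat, oxidative phosphorylation and fatty acid oxidation genes stood higher with vitamin D than in control aortas as lists, with few single genes called. Of 23 adipocyte genes 1 was called higher over all genes and 16 adjusted over the list alone (median 1.01; camera adjusted p = 9.1e-09, and adjusted p = 0.658 with an estimated correlation). The brown fat list had 0 of 9 called over all genes by limma and 6 adjusted over the list alone (median 1.06; camera adjusted p = 9.6e-06, and adjusted p = 0.658 with an estimated correlation). Oxidative phosphorylation (median 0.65, 0 of 31 over all genes, 20 adjusted over the list alone) and fatty acid oxidation (median 0.91, 0 of 24 over all genes, 20 adjusted over the list alone) went with them, with camera adjusted p = 6.8e-13 and 1.1e-11, and adjusted p = 0.658 with an estimated correlation for both. With the brown fat covariate in the fit of all 3 groups, chosen after the data were seen, these medians went from 0.65 to -0.03 and from 0.91 to -0.04. The median of 19 adipocyte genes outside the score went from 1.01 to -0.19. Ppargc1a, a coactivator of mitochondrial and thermogenic genes, averaged 24.1 ± 19.9 against 4.40 ± 1.85 FPKM, Cidea, a lipid droplet protein of brown fat, 606 ± 277 against 284 ± 134 FPKM, and Cox5a, a subunit of cytochrome oxidase, 69.3 ± 23.5 against 31.6 ± 10.6 FPKM; none of these passed the test over all genes. Interferon response genes stood lower with vitamin D (median -0.56, 0 of 24 over all genes, 13 lower adjusted over the list alone; camera adjusted p = 1.1e-11, and adjusted p = 0.541 with an estimated correlation). The antiviral gene Mx2 stood at 13.4 ± 7.84 against 34.4 ± 4.79 FPKM and Ifit1 at 4.52 ± 1.23 against 9.87 ± 1.75 FPKM.

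Single rats decided the count for vitamin D. Without control rat 41 limma called 0 genes, without control rats 42, 43 or 44 it called 2 in each case, and without control rat 46 it called 385. Leaving out a rat on vitamin D gave 1 without rat 36, 0 without rat 37, 4 without rat 38 and 393 without rat 39. Rises outnumbered falls in the larger counts, with 233 higher and 152 lower without rat 46 and 263 higher and 130 lower without rat 39. With array weights 264 were higher and 165 lower. All 13 called genes were free of overlap between the groups, as were 554 of all tested genes (5.72%; chance gives 1.59%). The authors' table lists 885 genes at q under 0.05, 521 higher and 364 lower; 883 of them were tested here, 10 were called in both, and in 74.6% of the 883 the libraries of the 2 groups overlapped. The same share of the authors' genes was 45.3% in uremic against control and 54.0% in uremic against control with vitamin D. Of 35 lists 12 were called with a preset correlation and none with an estimated one, and 7 were called without rat 37.

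The third comparison, uremic against control with vitamin D, asks what differs between uremic rats and rats with intact kidneys when both receive vitamin D. Dose, length of treatment, length of study and diet are not known to be equal. Most macrophage and complement genes and some bone and cartilage genes were higher in uremic aortas here too, and most mitochondrial and brown fat genes were lower. Mgp stood at 78679.5 ± 14872 (n = 5) against 12730.5 ± 3015 FPKM (n = 4), 6.18-fold higher (log2 2.63, SE 0.41, adjusted p = 0.0030). Spp1 was 4.80-fold higher (log2 2.58, SE 0.45), Sost 4.15-fold (log2 1.97, SE 0.35) and Ibsp 8.26-fold (log2 2.95, SE 0.24). Ucp1 fell from 153 ± 96.6 to 19.1 ± 13.9 FPKM (log2 -3.02, SE 0.52, adjusted p = 0.0047).

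In uremic aortas against those of control rats on vitamin D, 6 of 15 osteoblast and osteocyte genes rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.224 with an estimated correlation). Runx2 rose from 1.05 ± 0.487 to 6.02 ± 1.93 FPKM, Mepe from 0.277 ± 0.240 to 11.1 ± 5.42 FPKM, and Bmp4 from 27.0 ± 8.25 to 80.4 ± 19.0 FPKM. Of 9 chondrocyte genes 5 rose (6 rose and 1 fell adjusted over the list alone; median 1.94, camera adjusted p = 3.0e-05, and adjusted p = 0.0668 with an estimated correlation). Acan (aggrecan) stood at 0.581 ± 0.023 FPKM with vitamin D alone and 13.3 ± 7.28 FPKM in uremic aortas, and Comp at 32.6 ± 10.2 and 299 ± 104 FPKM. Of 13 calcification inhibitors and phosphate handling genes 7 rose (7 adjusted over the list alone; camera adjusted p = 1.1e-04, and adjusted p = 0.19 with an estimated correlation), among them Ankh (log2 1.85, SE 0.29) and Nt5e (log2 1.52, SE 0.22). Enpp1 rose by 1.35 (SE 0.29). Slc20a1 was called too (log2 0.91, SE 0.22, adjusted p = 0.0205), but not without uremic rat 28 or rats 36 or 38 on vitamin D (adjusted p up to 0.060). Col1a1 did not differ detectably (692 ± 434 against 648 ± 165 FPKM).

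Macrophage genes rose in 19 of 20 cases in uremic against control with vitamin D aortas (19 adjusted over the list alone; median 1.53, camera adjusted p = 4.9e-20, and adjusted p = 0.0668 with an estimated correlation). Lyz2 rose from 27.8 ± 13.0 to 263 ± 47.4 FPKM and Fcer1g, the signalling chain of Fc receptors, from 58.2 ± 6.21 to 171 ± 34.0 FPKM. The red blood cell list moved the same way, with a median of 1.93 and 1 of 7 called (6 adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.286 with an estimated correlation). Complement genes rose in 11 of 16 cases (13 adjusted over the list alone; camera adjusted p = 5.6e-09, and adjusted p = 0.135 with an estimated correlation). Serping1 stood at 651 ± 231 against 142 ± 15.1 FPKM. Of 7 osteoclast genes 3 rose (5 adjusted over the list alone; camera adjusted p = 7.1e-04, and adjusted p = 0.0668 with an estimated correlation), among them the bone protease Ctsk (cathepsin K), from 30.0 ± 6.71 to 98.2 ± 21.3 FPKM. In the FGF and Klotho list 5 of 14 rose (7 adjusted over the list alone; camera adjusted p = 1.6e-05, and adjusted p = 0.0668 with an estimated correlation), among them Etv4, from 0.441 ± 0.351 to 5.23 ± 1.66 FPKM. Ace, the angiotensin converting enzyme, rose from 12.1 ± 1.54 to 42.0 ± 10.5 FPKM, and Nr3c2, the mineralocorticoid receptor, fell from 7.29 ± 1.33 to 3.53 ± 0.707 FPKM.

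Mitochondrial genes were lower in uremic than in control with vitamin D aortas. Of 31 oxidative phosphorylation genes 30 fell (31 adjusted over the list alone; median -1.26, camera adjusted p = 4.7e-20, and adjusted p = 0.253 with an estimated correlation). Of 24 fatty acid oxidation genes 18 fell (20 adjusted over the list alone; median -1.62, camera adjusted p = 1.1e-11, and adjusted p = 0.262 with an estimated correlation). Ndufv1, a subunit of complex I, fell from 158 ± 51.6 to 53.7 ± 14.0 FPKM and the acyl-CoA dehydrogenase Acadm from 418 ± 162 to 114 ± 38.1 FPKM. Fat markers moved with them: 6 of 9 brown fat genes fell (8 adjusted over the list alone; median -1.80, camera adjusted p = 7.0e-06, and adjusted p = 0.262 with an estimated correlation). In the adipocyte list 10 of 23 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 5.9e-08, and adjusted p = 0.286 with an estimated correlation). Fatty acid synthase (Fasn) went down from 113 ± 58.7 to 16.0 ± 14.9 FPKM. With the brown fat score of each library as a covariate, chosen after the data were seen, 0 of the 49 falls among these oxidative phosphorylation and fatty acid oxidation genes in the fit of all 3 groups remained called by limma. In that fit the number of genes called in this comparison was 1658 without the covariate and 475 with it. The median of 19 adipocyte genes outside the score turned from -1.21 to 0.50 with the covariate. Of these, 8 were called without and 2 with it. Contractile smooth muscle genes were lower in 6 of 24 cases (7 adjusted over the list alone, median -0.53, camera adjusted p = 1.6e-05, and adjusted p = 0.373 with an estimated correlation). With the brown fat covariate in the fit of all 3 groups their median went from -0.53 to -1.06, and the members called from 8 to 11. The smooth muscle coactivator Myocd stood at 22.1 ± 8.25 against 53.6 ± 17.8 FPKM (adjusted p = 0.0159, and up to 0.056 without rat 36 or rat 38 on vitamin D, which ended the call).

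**Figure D2:**
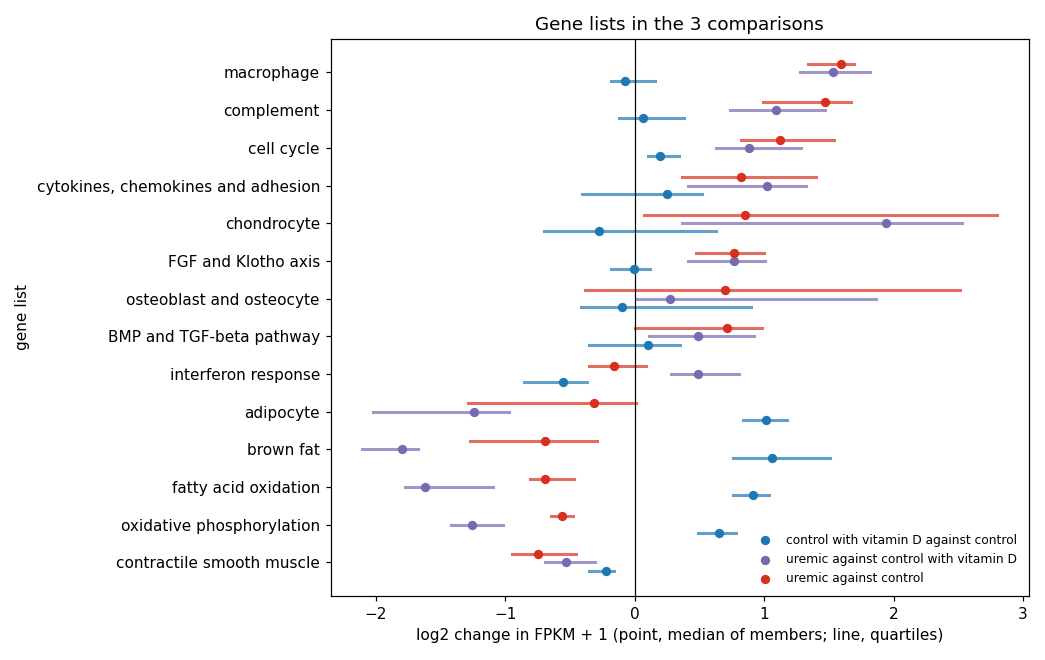
Median (points) and quartiles (lines) of the log2 change in FPKM + 1 over the tested members of 14 gene lists, for the 3 comparisons. Macrophage, complement and cell cycle genes lie to the right of 0 in both comparisons of uremic aortas, and adipocyte, brown fat, fatty acid oxidation and oxidative phosphorylation genes lie on opposite sides for control with vitamin D against control and for uremic against control with vitamin D.

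Over all genes, limma called 1311 of 9916 between uremic aortas and those of control rats on vitamin D, 713 higher and 598 lower, of which 347 and 243 changed by at least 1 on the log2 scale. In 1264 genes (12.7%; chance gives 1.59%) the libraries of the groups did not overlap. The authors' table lists 1631 genes at q under 0.05, 787 higher and 844 lower; 1036 were called in both, all in the same direction. Of 35 lists 24 were called with a preset correlation and none with an estimated one. With every library scaled to the same total the median over all genes moved to -0.12, and 33.6% of the called genes were higher, against 54.4% as deposited. The count fell to 871 without uremic rat 9, 857 without uremic rat 20, 659 without rat 36 and 708 without rat 38 on vitamin D. The exact rank-sum test called 0 genes after adjustment here as well, where limma called 1311. Before adjustment, 2851 genes had a p under 0.05 in limma.

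The comparisons against control share the 5 control libraries. Among 9637 genes tested in both, 13 were called in both, 1 higher in both (Cfd) and 12 lower in both, which are all of the vitamin D calls; independent lists of these sizes would share 0.10 and 1.3. With the control libraries divided between the comparisons (2 and 3, all 20 assignments), limma called any gene for vitamin D in only 6 of them. With 9, 32 and 8 vitamin D calls, 6, 10 and 5 were lower in both, against 0.175, 0.377 and 0.173 for independent lists; the other 3 divisions had 1 call each, and it was shared in 2 of them. These divisions use the same rats again and are not independent. Across genes, the changes correlated at r = 0.384 and had a covariance of 0.0719. Simulated libraries without any change gave a mean r of 0.474 and a mean covariance of 0.0203. There the controls were simulated too and shared by both comparisons, and each gene varied on its own, without the correlation between genes of the real libraries. With the controls divided, so that none is shared, the median r was 0.231 (0.135 to 0.315 over the 20 divisions) and the median covariance 0.0487. For Jund the change was -0.98 with vitamin D and -1.89 in uremic aortas, and for Rcor2 -1.36 and -2.66.

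**Figure D3:**
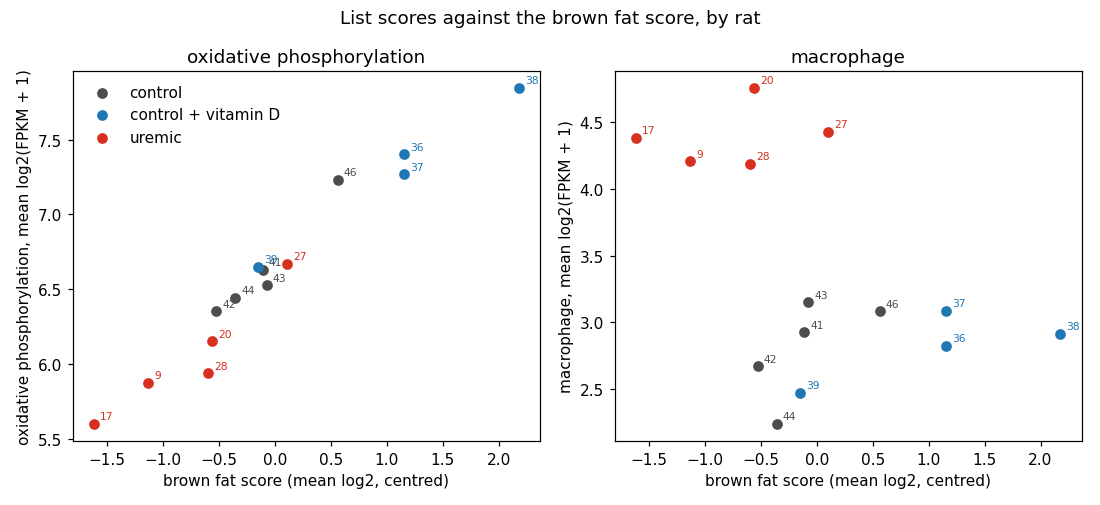
List scores (mean log2 of FPKM + 1 over members) of oxidative phosphorylation (left) and macrophage genes (right) against the brown fat score of each library, by rat and group. The oxidative phosphorylation score climbs with the brown fat score over the 14 libraries, while the macrophage score of each of the 5 uremic libraries lies above that of the other 9.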

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

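Both tests of the pattern in rat 37 given here were chosen after the result was seen. In 48 of 419 groups, the gap of 1 rat to the next, over the range of its group, passed Dixon's critical value. The groups, of 4 or 5 rats, came from 98 genes (among them all that the text names), 37 list scores and library measures. For independent groups of normally distributed values, chance flags about 1 in 20, or 20.95 here. Genes that vary together are not independent, and FPKM need not be normally distributed, so the 48 are not a measured excess over chance. Rat 37 accounted for 13 of the 48, rat 46 for 10 and rat 27 for 8.

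Rat 37, a control rat on vitamin D, lay far above the rest of its group in 12 genes. It had 11.7 FPKM of Olr1 (at most 1.20 in the other 3 rats), 23.6 of Thbs1 (2.66), 936 of Fn1 (384) and 9.39 of Pnoc (1.63). It also had 3281 of Spp1 (789), 30.1 of Mt2A (5.17), 17229 of Mgp (11628.5) and 13.8 of Enpp1 (5.97). The remaining genes were Postn (418, next 148), Timp1 (131, next 34.8), Icam1 (27.9, next 10.5) and Il6 (2.76, and 0 in the other 3). Its cell cycle score of 1.88 was also the highest, with 0.777 as the next.

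Rat 37 lies towards the uremic libraries in these genes, but uremic RNA mixed into the library would give 1 share over 13 abundant uremic genes. Instead, Mgp implied 8.89% of uremic RNA and Spp1 43.9%, with 0.742% (Gpx3) and 101% (Timp1) as the extremes. A whole uremic library under this label is argued against too: rat 37 reached the lowest uremic library in 1 of the 13 genes (Timp1), although it lay above the other 3 rats on vitamin D in 12. The cause stays open.

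Rat 27, uremic, had 551 FPKM of Cyp2e1 (at most 72.2 in the other 4), 98.8 of Gstm7 (18.8), 363 of Cfd (111), 445 of Cidea (186), 49.0 of Cox5a (23.2) and 24.3 of Ppargc1a (8.62). It had the lowest osteoclast score (2.83, next 3.04) and a relative depth of 2.64 (next 1.34). Rat 46, a control, had 10.4 FPKM of Slc7a15 (next 5.15), 153 of Acaa2 (64.5) and 44.0 of RGD1309708 (21.6). It was also far above the other controls in Acadm (493, next 214), Cidea (519.5, next 261), Cox5a (49.9, next 29.9), Cyc1 (62.5, next 46.3) and Ndufv1 (175, next 89.2). It had the highest fatty acid oxidation score (5.78, next 5.02) and the lowest circadian clock score (3.78, next 4.57). The clock scores of the other controls (4.57 to 4.76) lay above those of all uremic rats (3.95 to 4.21) and all rats on vitamin D (3.94 to 4.37). Most controls thus differed from both other groups in clock genes, and the cause was not tested. The clock list was not called in uremic against control (camera adjusted p = 0.291) or control with vitamin D against control (camera adjusted p = 0.337).

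Control rat 43 had 2698 FPKM of Hba2 (next 479), 27.6 of Hbb-b1 (8.05), 51.6 of Alas2 (8.56), 8.87 of S100a9 (2.57) and 2.43 of Thbs1 (1.22), most of them genes of blood cells. Further values far from their group were Rcor2 in control rat 44 (63.2, next 42.2) and Col3a1 in control rat 44 (1223, the lowest, next 1557). In uremic rats these were Serping1 in rat 17 (1060.9 FPKM, next 584), Gpnmb in rat 17 (109.9, next 69.1), Prg4 in rat 17 (185, next 82.1), Bmp4 in rat 9 (113, next 78.5), Hspa1b in rat 28 (28.2, next 11.8) and Fasn in rat 20 (42.3, next 12.2). Among the rats on vitamin D, rat 38 had the lowest osteoblast and osteocyte score (4.30, next 4.36). Rat 39 had the highest scores of the Wnt pathway (3.79, next 3.50) and of T and NK lymphocytes (1.72, next 1.44), and rat 36 the lowest vitamin D response score (3.13, next 3.56).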

How the results depend on the processing

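The brown fat covariate, voom and the restriction to recovered reads were chosen after the data were seen; the other alternatives were planned. Uremic against control called 2177 genes. Requiring a log2 change of at least 1 left 669 by its construction, and the exact rank-sum test called 0. All other settings gave from 1667 (mean of at least 5 FPKM) to 2733 (array weights) genes, and those leaving out 1 rat 1684 to 2224. Control with vitamin D against control, 13 genes, gave 3 with no filter on low values (more genes tested), 8 under quantile normalization, 429 with array weights and 7 at a log2 change of at least 1. The exact rank-sum test called 0. In the fit of all 3 groups the count was 14 without and 26 with the brown fat covariate (5 of the 26 among the 13). It was 8 with voom, 6 among genes with recovered reads, and 0 to 393 when 1 rat was left out. Uremic against control with vitamin D, 1311 genes, gave 1999 with array weights, 590 at a log2 change of at least 1, 0 in the exact rank-sum test and 659 to 1662 when 1 rat was left out. In the fit of all 3 groups it gave 1658 without and 475 with the brown fat covariate. Apart from the minimum change, the cause was not tested. With 5 against 5 or 4 against 5 rats the rank-sum test has few possible p values, the smallest of which did not survive adjustment.

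List calls with an estimated correlation were 0 in all 3 comparisons, against 19 (uremic against control), 12 (control with vitamin D against control) and 24 (uremic against control with vitamin D). Fry on direction called 16, 1 and 22 lists, and fry on change in either direction 31, 15 and 32. Leaving out 1 rat gave 15 to 19, 7 to 12 and 22 to 25 calls. The number of genes called in both comparisons against control was 10 with a pseudocount of 0.1 and had a median of 0 over the 20 divisions of the control rats between the comparisons. In all but 6 of these divisions, with fewer rats in each fit, no gene was called for vitamin D, so none could be shared.

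Genes not called with all rats, whose sign turned in control with vitamin D against control when 1 rat was left out, had these log2 changes: Acta2 -0.18 to 0.064, Enpp1 -0.39 to 0.042, Slc20a1 -0.21 to 0.062 and Acp5 -0.34 to 0.0032. The others were Mpo -0.19 to 0.68, S100a8 -0.045 to 0.27, Actc1 -0.23 to 0.016, Hbb-b1 -0.76 to 0.30, Alas2 -0.90 to 0.37, Hba2 -0.50 to 0.86 and Plk1 -0.041 to 0.36. In uremic against control with vitamin D these were Bmp2 (-0.31 to 0.28, and 0.016 with a pseudocount of 0.1), Col1a1 (-0.41 to 0.20) and S100a9 (-0.048 to 0.79); the cause was not tested. No named gene turned its sign in uremic against control under a pseudocount of 0.1, median-ratio scaling or a left-out rat. Of the named calls, 118 of 132 (uremic against control), 0 of 11 (control with vitamin D against control) and 90 of 125 (uremic against control with vitamin D) held without every single rat. The planned test for whole reads other than limma was not run.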

Other observations

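The brown fat covariate, the test of lymphoid tissue, the splits singled out and the lists of heat shock and MHC genes were chosen after the data were seen. The predictions for the brown fat covariate, the scaling, the blood and the counts over the splits were written before their results. That for lymphoid tissue was written after. The adjusted p values of the heat shock and MHC lists cover them and the planned lists together, 38 in each comparison, and none of them passed with an estimated correlation. This adjustment does not correct for the choice of these lists from the same data, so their p values are descriptive only. Genes of MHC class II, which present antigen to T cells, were far higher in uremic aortas. In uremic against control, all 6 tested members rose (6 adjusted over the list alone; median 3.08 on the log2 scale, camera adjusted p = 8.1e-09, and adjusted p = 0.133 with an estimated correlation). Cd74, the invariant chain, rose from 28.3 ± 10.3 to 358 ± 149 FPKM (n = 5 each), RT1-Da from 4.99 ± 0.848 to 50.0 ± 15.7 FPKM and Ciita, the class II transactivator, from 0.213 ± 0.187 to 1.38 ± 0.530 FPKM. Against control with vitamin D all 6 rose too (median 2.91, camera adjusted p = 8.3e-09, and adjusted p = 0.123 with an estimated correlation), while 0 of 5 passed limma's test in control with vitamin D against control (0 adjusted over the list alone). Of 10 MHC class I genes, 3 rose in uremic against control, although the list was not called (camera adjusted p = 0.0508, and adjusted p = 0.441 with an estimated correlation). In uremic against control with vitamin D the list was called (camera adjusted p = 0.00733, and adjusted p = 0.272 with an estimated correlation), with 1 of 10 members higher (2 adjusted over the list alone). The class I gene B2m rose in uremic against control, from 805 ± 70.6 to 1210.0 ± 191 FPKM.

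Many heat shock genes were lower in uremic aortas. In uremic against control with vitamin D, 13 of 16 fell (14 adjusted over the list alone; median -1.43, camera adjusted p = 3.2e-12, and adjusted p = 0.107 with an estimated correlation). In uremic against control 9 of 16 fell (11 adjusted over the list alone; median -0.77, camera adjusted p = 3.6e-05, and adjusted p = 0.31 with an estimated correlation). Hspa1b, an inducible chaperone of the HSP70 family, averaged 13.3 ± 8.52 FPKM in uremic, 136 ± 55.4 FPKM in control with vitamin D and 126 ± 108 FPKM in control aortas. Dnajb4, a cochaperone, averaged 228 ± 92.4 FPKM in control aortas and changed by -1.47 on the log2 scale (SE 0.23) in uremic against control. In control with vitamin D against control 0 of 16 passed limma's test over all genes (3 adjusted over the list alone), but the list was called higher (median 0.44, camera adjusted p = 0.00759, and adjusted p = 0.739 with an estimated correlation).

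Oxidative phosphorylation and fatty acid oxidation genes were lower in uremic aortas than in those of control rats on vitamin D (median -1.32 over 55 members). Different amounts of brown fat around the dissected aortas may account for most of this, but the covariate cannot decide it. The score itself holds Ppargc1a, a coactivator of mitochondrial genes, and Cox8b, a subunit of cytochrome oxidase. Lower expression of mitochondrial genes without less fat could therefore lower the score too. With the brown fat score as a covariate 11.4% of the median change was left (-0.15), the falls called by limma went from 49 to 0, and the members correlated with the score within groups (median r 0.893, against -0.022 for all genes). The scaling of the libraries is argued against as the cause, since the highest median under median-ratio, quantile and equal-total scaling was -1.21. Whether vitamin D or uremia changed the fat itself, or mitochondrial genes without the fat, stays open. So does whether dissection left more fat, although the protocol removed connective tissue. The same covariate left 19 of 24 contractile smooth muscle genes called in uremic against control, and 14 were called without it in the same fit.

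Macrophage genes were higher in uremic than in control aortas. More blood left in the vessel, which the protocol rinsed with saline, is argued against: with the red blood cell score as a covariate 86.0% of the median change was left (1.37 of 1.60) and 18 of 20 genes stayed called. For lymphoid tissue in the uremic dissections the rule for arguing against it was met, but only narrowly, and it does not decide the question. The summed FPKM of 31 T, NK, B and plasma cell markers was 18.5 ± 11.9 in uremic and 13.0 ± 5.66 in control aortas. The log2 ratio of these means was 0.508. A 95% interval from -0.732 to 1.51 belongs to the difference in mean log2 of the sums, not to that ratio. The upper end of this interval lies just below the macrophage median of 1.60, and no interval was computed for that median or for the ratio of means. The lower quartile of the macrophage members, 1.33, lies within the interval. The T and NK lymphocyte score ran from 1.15 to 2.65 in uremic and from 1.09 to 2.09 in control rats. Lymphoid tissue, more macrophages in the wall, or higher expression per cell remain as hypotheses that these libraries cannot separate.

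Chance as the source of the counts was tested by dividing the same libraries in other ways. For uremic against control, 1 of 100 splits called as many genes as the real one (2177), which was the real split itself. The highest other called 6, which argues against chance. For uremic against control with vitamin D it was again 1 of 100 (real 1311, highest other 1064), below the share of 5% fixed beforehand, which argues against chance. The split with 1064 moved uremic rat 27 to the rats on vitamin D, and another, with 472, exchanged rat 27 and rat 39. The size of this count therefore also depends on a structure of the samples. For control with vitamin D against control 3 of 100 splits called at least 13 genes, below the share of 5% fixed beforehand. Chance is not excluded for this count, since the highest other called 473, several times the real count, which points to a structure of the samples. That split exchanged control rat 46 and rat 39 on vitamin D, and the next, with 373 genes, set control rat 46 with the rats on vitamin D; the brown fat score was 0.56 in rat 46, the highest of the controls, and -0.15 in rat 39, the lowest of its group.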
